A study of Homo sapiens with 126 samples.

How the data were processed

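RNA of 42 human lymphoblastoid cell lines was measured on Illumina HumanRef-8 v3.0 arrays, with 1 array each of unfractionated, light (nonpolysomal) and heavy (polysomal) RNA per line, 126 arrays in all. Per the labels, cells were treated with cycloheximide, lysates were separated on sucrose gradients, and fractions before the monosome peak were pooled as nonpolysomal and fractions after it as polysomal RNA. Groups and pairs were taken from the fraction and cell line that the labels give. Line names, and any detail of the people the lines came from, were not used beyond pairing the 3 arrays of a line, and values are given only as summaries over lines.

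The deposited unnormalized table holds, per gene and array, an intensity on a linear scale with no background subtracted, which the authors made with BeadStudio. Per the file headers, it also gives a detection p-value against negative control beads, other values for the standard error of bead intensities and other values for the mean number of beads. Its rows are genes: 14448 carry a single probe and 3872 average several. The authors' processed values, made with lumi, are on a log2-like scale, kept the order of the raw signals within each array, and had array medians near 7.52; the transform and normalization used are not stated. The deposited table of ratios gives another unit, a log ratio of polysomal to nonpolysomal RNA per line and gene, with base and scale not stated by the authors.

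The analysis used R 4.3.3 with limma 3.58.1, the data.table package (version 1.17.8) and jsonlite 2.0.0. Of 18401 gene rows, 81 sex-linked rows were left out before any step and 18320 were used. Left out were rows named XIST, TSIX, JPX or FTX and rows annotated to the Y chromosome. JPX and FTX are on the fixed list of noncoding RNAs and were thus not tested. Symbols are those of the files; 18072 rows matched a current symbol of the reference annotation by Entrez identifier and 3150 of these had changed name, and current names are given where they help. Background was fitted as in limma's neqc from the detection p-values, on single-probe rows only because an averaged row has a narrower noise, followed by the normal-exponential correction, an offset of 16, quantile normalization over all 126 arrays and log2. The background mean had medians of 58.6, 57.1 and 60.7 and its SD 6.33, 5.90 and 6.92 in unfractionated, light and heavy arrays, and genes were read from a median of 40 beads. The number of arrays limits the precision. No column of values was left without a sample, and 0 pairs of arrays were identical.

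A gene entered a comparison when its detection p was under 0.01 on at least 50% of the arrays of 1 of the groups compared. The heavy and light, heavy and unfractionated, and light and unfractionated arrays were each fitted with limma on paired differences, with the line as the replicate block. Genes differing from 0 were called by eBayes and genes past 1.5-fold by treat, both at a Benjamini-Hochberg adjusted p under 0.05; errors given with ± on log2 differences are standard errors over 42 lines unless named SD. Gene lists, 33 in number, were fixed before the data were examined and those with at least 5 genes tested went to limma's camera with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The distance of a fraction from unfractionated RNA was a root mean square over genes per line, compared by a two-sided sign-flip permutation test with 100000 resamples. The slope of the ratio on the unfractionated level was fitted per gene across lines with limma's moderated variance. For a ratio named in the text whose gene was detected on no array of a fraction, a bound taken against the light or heavy detection limit is given. Counts and list medians used the fitted ratios of such genes.

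Genes named in the text follow a rule set before the data were examined: the 12 highest and 12 lowest ratios past 1.5-fold, for each list the 3 genes with the smallest p and the 1 going farthest against the list's median, 7 fixed genes, the 5 highest and 5 lowest against unfractionated RNA, the 8 largest between-line SDs among genes detected on at least 90% of heavy and of light arrays, and the 5 smallest slope p-values in each direction. FTH1, one of the fixed genes, has no row of that name, and a few genes that the rule names are left out of the text and of the plot of named genes. The rule's choice of 1 probe per gene was met by the files, whose rows are already genes.

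Pairing was checked through each array's deviation from its fraction's mean. Heavy and light arrays of a line correlated with a median of 0.722 (lowest 0.269), against -0.025 for arrays of other lines, and 41 of 42 heavy arrays were closest to the light array of their own line; for heavy with unfractionated and for light with unfractionated arrays, 42 of 42 were. The same fit was tested on simulated data of 10920 genes: of 100 genes shifted 2-fold, 100% differed from 0 and 94% passed 1.5-fold; of 100 genes shifted 4-fold, 100% passed; of 10521 unshifted genes, 13 differed from 0 and 0 passed 1.5-fold. Of 199 genes given a slope of 0.7, 54.3% were called, with 15 of 10721 others, and a list drawn from unshifted genes had a camera p of 0.666. Noise was simulated independently for each gene, so this list does not test camera where the genes of a list are correlated. Apart from the shifted genes, heavy and light RNA had the same simulated mean level. The slope calls thus do not test dim signals that draw a ratio towards 0. Unfractionated RNA was given less noise than the fractions, so the share of slopes called need not carry over to the real arrays.

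Alternatives were another background and normalization (quantile normalization of raw log2 signals, a median shift only, the authors' processed values), no filter and a filter for detection on every array, only the 38 lines of the deposited ratio table, a fit without the replicate block, treat at 1.2-fold and 2-fold, camera with an estimated correlation, removal of the first principal component from the slopes, and Spearman in place of Pearson correlation. Of the rows used, 28 had no match in the authors' processed values and 22 none in the ratio table. Background fitted on all rows, detection by signal over background mean plus 3 SDs, and 40 lines without the 2 that held the 4 arrays standing apart from their fraction (by over 3 median absolute deviations in correlation) were chosen after seeing the data. Fractions were also swapped at random within lines in 100 draws for each count of genes or lists, and the order of the lines permuted 100 times for the slopes.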

Results

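The series profiled RNA from 42 human lymphoblastoid cell lines, which are B cells made to grow in culture by Epstein-Barr virus. Each line gave 3 arrays, for 126 samples in all: 1 of unfractionated RNA, 1 of the light fraction of a sucrose gradient, pooled ahead of the monosome peak, and 1 of the heavy fraction, pooled after it, which holds messages on polysomes. Per the labels, equal amounts of polyadenylated RNA from the 3 preparations went onto the arrays, so a ratio between fractions compares shares of each preparation and not amounts per cell. The median signal per array was 63.5 to 113 for unfractionated RNA, 60.9 to 100.5 for the light fraction and 66.2 to 117 for the heavy fraction, over a fitted background whose median was 58.6, 57.1 and 60.7. The share of genes detected per array had medians of 52.6%, 48.3% and 52.6%, with a lowest value of 43.2% in the light fraction and a highest of 58.0% in unfractionated RNA. The first principal component of all arrays held 29.5% of the variance and parted the 3 preparations without overlap: heavy arrays lay between 24.9 and 47.8, unfractionated arrays between -14.3 and 7.87, and light arrays between -48.5 and -29.9.

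The comparison of the heavy with the light fraction asked which messages sat on polysomes and which stayed off them, the quantity that the study took per line as its measure of translation. Messages for ribosomal proteins and for other listed genes with a 5' terminal oligopyrimidine tract lay low in the heavy fraction. Messages for the proteasome, which degrades proteins, lay high. Of 74 cytosolic ribosomal protein genes tested, 65 were lower in the heavy fraction, 7 were higher and 2 differed by less than the test could call; the median log2 ratio was -1.22, against 0.07 over all genes tested. Of 21 other listed genes whose messages carry a 5' terminal oligopyrimidine tract, 18 were lower and 3 higher, with a median of -1.05. Not all genes on this list serve translation: it holds the chaperonin subunit CCT2, for example. All 38 proteasome subunit genes tested were higher, with a median of 1.18.

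Among the ribosomal protein genes, RPL23A (-3.54 ± 0.06, log2 ratio with its SE, n = 42 lines), RPL22 (-2.99 ± 0.05) and RPL13A (-2.52 ± 0.04) were lower in the heavy fraction in all 42 lines, while RPL6 went the other way in all 42 (1.78 ± 0.07). Among the other oligopyrimidine tract genes PABPC1, the cytoplasmic poly(A)-binding protein, lay at -2.995 ± 0.06. The initiation factor 3 subunits EIF3EIP and EIF3H lay at -2.31 ± 0.05 and -2.17 ± 0.04. The chaperonin subunit CCT2 was higher (0.79 ± 0.08) in 39 of 42 lines. PSMB3 (2.44 ± 0.05), PSMB1 (1.75 ± 0.03) and PSME2, a subunit of the proteasome activator (2.41 ± 0.05), were higher in all 42 lines. These 3 groups were also called by the competitive test against all other genes, with adjusted p = 8.59e-16 for ribosomal proteins, 3.02e-06 for the other oligopyrimidine tract genes and 7.56e-12 for the proteasome. The calls were lost when the correlation between genes was estimated from the lines: adjusted p = 0.128 with an estimated correlation for ribosomal proteins, adjusted p = 0.175 with an estimated correlation for the other oligopyrimidine tract genes and adjusted p = 0.127 with an estimated correlation for the proteasome.

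**Figure D1:**
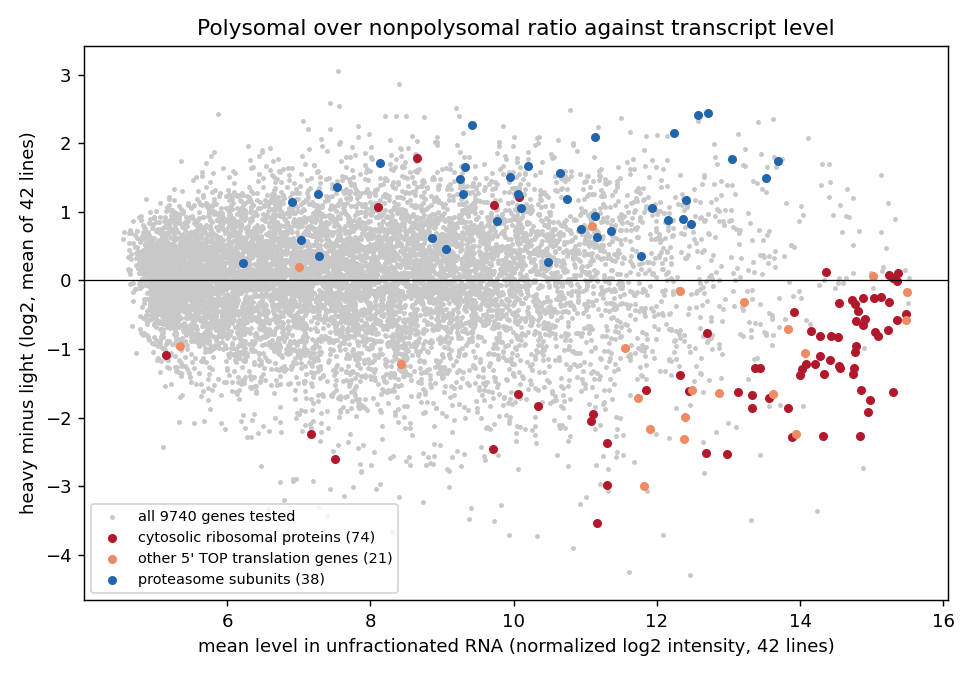
Heavy minus light log2 ratio of each of 9740 genes (mean of 42 lines) against its mean normalized log2 intensity in unfractionated RNA, with ribosomal protein genes, other 5' TOP translation genes and proteasome subunits coloured. The 38 proteasome subunits all lie above 0, and 65 of the 74 ribosomal protein genes were called lower.

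Genes of cell division lay higher in the heavy fraction. Of 42 genes of DNA replication, 30 were higher and 3 lower (median 0.56; adjusted p = 0.000231, and adjusted p = 0.128 with an estimated correlation). Thymidine kinase TK1 (2.09 ± 0.04), the clamp loader subunit RFC2 (1.52 ± 0.04) and the sliding clamp PCNA (1.51 ± 0.05) were higher in all 42 lines, while the licensing factor CDT1 lay at -1.06 ± 0.08. Of 49 genes of mitosis and the spindle, 39 were higher and 7 lower (median 0.56, and 0.25 with the authors' processed values, 0.26 with the background fitted on all rows and 1.23 with a median shift; adjusted p = 0.000323, and adjusted p = 0.175 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was higher (1.62 ± 0.05), as was CDCA3 (1.14 ± 0.04), and the centromere protein gene CENPN was lower (-1.89 ± 0.05) in all 42 lines.

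Groups that build ribosomes, charge transfer RNAs and run mitochondria leaned to the heavy fraction with members on both sides. Of 57 ribosome biogenesis genes, 39 were higher and 12 lower (median 0.60, and 0.23 with the authors' processed values, 0.25 with the background fitted on all rows and 1.17 with a median shift; adjusted p = 0.00582, and adjusted p = 0.330 with an estimated correlation). EBNA1BP2 lay at 2.37 ± 0.04 and IMP3 at 1.51 ± 0.04 against the RNA polymerase subunit POLR1D at -2.18 ± 0.05. Of 19 aminoacyl-tRNA synthetases, 15 were higher and 3 lower (median 0.44; adjusted p = 0.0172, and adjusted p = 0.389 with an estimated correlation); alanyl-tRNA synthetase AARS (1.26 ± 0.05) and FARSA (0.83 ± 0.04) were higher, and glutaminyl-tRNA synthetase QARS was lower (-1.62 ± 0.04). Of 71 mitochondrial ribosomal protein genes, 47 were higher and 19 lower (median 0.43; adjusted p = 0.0338, and adjusted p = 0.507 with an estimated correlation), from MRPL24 (2.00 ± 0.04) and MRPL22 (1.89 ± 0.04) to MRPL53 (-2.15 ± 0.07). Of 70 nuclear genes of oxidative phosphorylation, 44 were higher and 18 lower (median 0.39; adjusted p = 0.0410, and adjusted p = 0.507 with an estimated correlation), from UQCRC1 (1.88 ± 0.04) and NDUFB8 (1.84 ± 0.04) to ATP5I (-1.81 ± 0.06). Of 15 genes of antigen presentation by MHC class I, 12 were higher and 2 lower (median 0.52; adjusted p = 0.0349, and adjusted p = 0.175 with an estimated correlation). HLA-F (1.54 ± 0.05) and HLA-G (1.30 ± 0.05) were higher, and the peptide-trimming enzyme LRAP was lower (-0.90 ± 0.08) in 40 of 42 lines. With a median shift in place of quantile normalization the class I and the oxidative phosphorylation groups were not called (adjusted p = 0.0612 and 0.0918). The oxidative phosphorylation call was also lost in the 38 lines of the deposited ratios (adjusted p = 0.0511) and with detection by signal over background (adjusted p = 0.0691).

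Of the 33 gene lists fixed before the data were examined, 31 had enough members for the competitive test, 8 were called higher and 2 lower, and the other 21 were not called. Limma's camera with an estimated correlation called 0 lists at an adjusted p of 0.05, with 7 at an unadjusted p under 0.05. Limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 30 of the 31 lists, and its mixed form, which counts changes in either direction, passed 31. For every list the number of its genes called was the same adjusted over the list alone as adjusted over all genes tested.

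**Figure D2:**
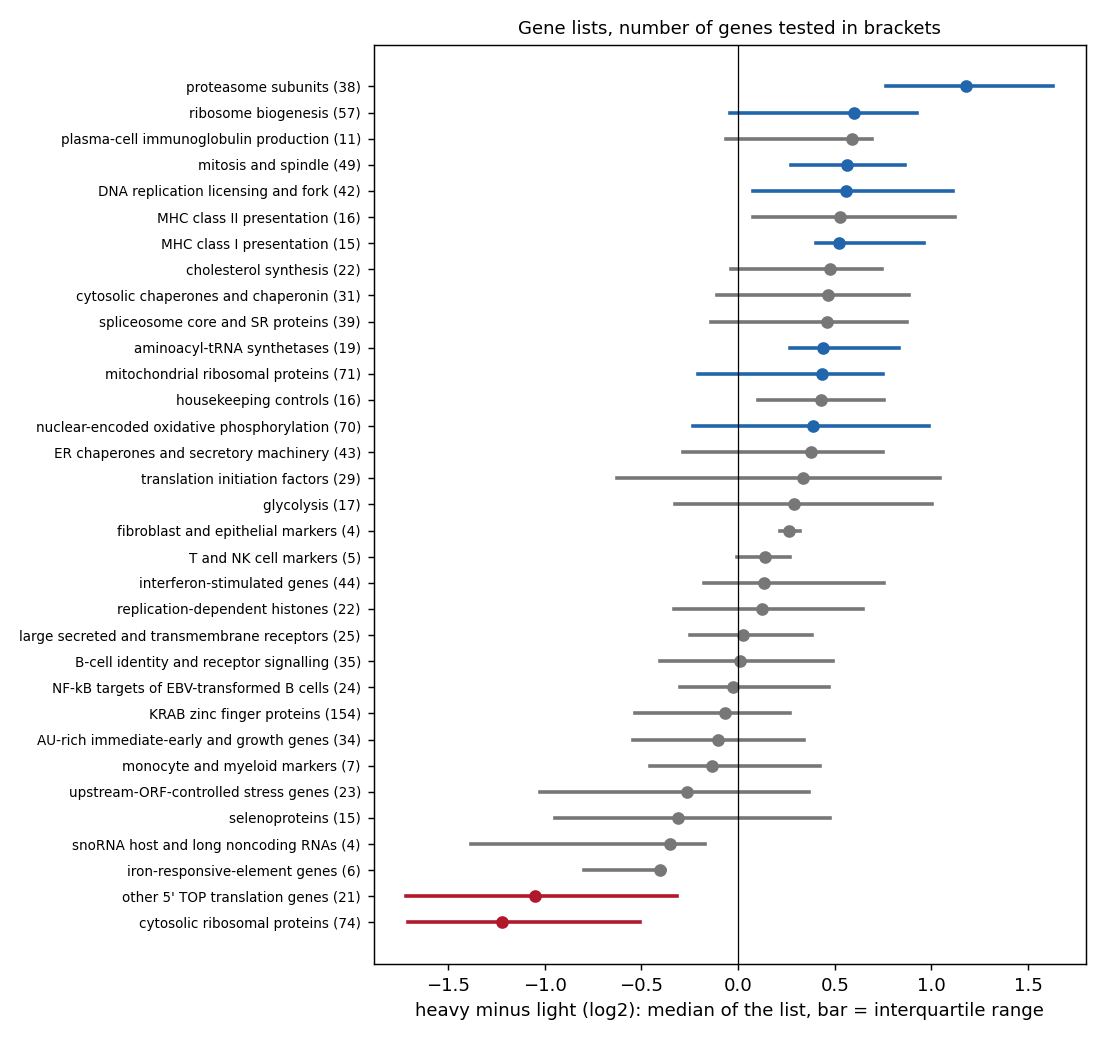
Median log2 heavy over light ratio of each of 33 gene lists (point) with its interquartile range (bar), the number of genes tested in brackets; blue lists were called higher and red lists lower by the competitive test with a preset correlation. Proteasome subunits stand highest with a median of 1.18 and cytosolic ribosomal proteins lowest with -1.22; the KRAB zinc finger median of -0.07 becomes 0.17 with a median shift, where the median of all genes goes from 0.07 to 0.46.

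Stress, iron and selenium genes held large single shifts in lists that were not called. ATF4, the transcription factor of the integrated stress response whose message carries upstream reading frames, lay at -2.24 ± 0.06 and the polyamine enzyme AMD1 at -1.96 ± 0.04, while UCHL1 was higher (1.77 ± 0.05). Of 23 genes with upstream reading frames, 8 were higher and 12 lower (median -0.27, and 0.12 with a median shift; adjusted p = 0.206). FTL, the ferritin light chain, lay at -2.73 ± 0.07 and the iron transporter SLC11A2 at -0.92 ± 0.05. Of 6 genes with iron-responsive elements, 1 was higher and 5 lower (median -0.40; adjusted p = 0.0897). The glutathione peroxidases GPX4 (-2.48 ± 0.06) and GPX1 (-1.80 ± 0.06) and the selenoprotein SEPW1 (-3.16 ± 0.08) were lower in all 42 lines, while the thioredoxin reductase TXNRD2 was higher (1.64 ± 0.08). Of 15 selenoprotein genes, 6 were higher and 9 lower (median -0.31, and 0.42 with a median shift; adjusted p = 0.307).

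B-cell and immune genes went both ways. Of 35 genes of B-cell identity and receptor signalling, 13 were higher and 12 lower (median 0.01, and 0.75 with a median shift; adjusted p = 0.953). The receptor TNFRSF17 (1.59 ± 0.05), the antigen receptor chain CD79A (1.31 ± 0.05) and FCRLA (1.41 ± 0.06) were higher, and the tetraspanin CD37 was lower (-2.16 ± 0.09). Of 24 NF-kB targets, 11 were higher and 10 lower (median -0.03, and 0.63 with a median shift; mean 0.01; adjusted p = 0.952). The cytokine TNF lay at -2.10 ± 0.05, the apoptosis inhibitor BIRC3 at -1.45 ± 0.05 and the inhibitor NFKBIE at 1.33 ± 0.04. Of 44 interferon-stimulated genes, 22 were higher and 13 lower (median 0.13, and 0.80 with a median shift, where the list was called; adjusted p = 0.266); ISG20 (1.80 ± 0.05), ISG15 (1.76 ± 0.05) and IFI35 (1.45 ± 0.05) were higher and XAF1 lower (-1.38 ± 0.07). Of 16 class II presentation genes, 11 were higher and 3 lower (median 0.53; adjusted p = 0.0610). HLA-DRB1 lay at 1.86 ± 0.06 and HLA-DPB1 at -1.02 ± 0.06. Of 34 immediate-early and growth genes with AU-rich elements, 14 were higher and 17 lower (median -0.10, and 0.51 with a median shift; adjusted p = 0.302), among them the suppressor SOCS1 (-1.53 ± 0.06), the decay factor ZFP36 (-1.61 ± 0.07) and the cyclin CCND3 (1.06 ± 0.05).

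Among lists of general cell machinery, 26 of 39 spliceosome genes were higher and 10 lower (median 0.46; adjusted p = 0.0584, and called higher under 6 alternatives, with medians from 0.23 to 1.11). SNRPB lay at 2.11 ± 0.04 and SF3A2 at -1.87 ± 0.10. Of 31 cytosolic chaperones, 21 were higher and 8 lower (median 0.47; adjusted p = 0.0920). PFDN6 lay at 2.39 ± 0.06 and PFDN5 at -1.13 ± 0.04. Of 43 genes of the secretory machinery, 28 were higher and 13 lower (median 0.38; adjusted p = 0.0897). SRP14 lay at 1.99 ± 0.06 and SEC11A at -1.13 ± 0.04. Of 17 glycolysis genes, 10 were higher and 5 lower (median 0.29; adjusted p = 0.197). PGAM1 (2.10 ± 0.05), TPI1 (2.08 ± 0.05) and ENO1 (1.21 ± 0.03) were higher in all 42 lines, and HK2 lay at -0.56 ± 0.05 but at 0.23 with a median shift. Of 29 initiation factor genes, 17 were higher and 10 lower (median 0.34; adjusted p = 0.383). The initiation factor median was 0.12 with the authors' processed values, 0.12 with the background fitted on all rows and 0.81 with a median shift. EIF5 lay at 1.62 ± 0.06, the helicase EIF4A1 at 1.09 ± 0.04 and EIF2A at -2.17 ± 0.06. Of 22 cholesterol synthesis genes, 14 were higher and 5 lower (median 0.48; adjusted p = 0.103). EBP lay at 1.45 ± 0.07 and SC5DL at -1.07 ± 0.07. Of 22 replication-dependent histone genes, 11 were higher and 7 lower (median 0.12; adjusted p = 0.576). Among genes detected on every array their median was 0.69 and the list was called, and with no filter it was -0.003. HIST1H1C lay at 2.13 ± 0.05 and HIST1H2BJ at -1.54 ± 0.07. Of 25 genes of large receptors, 11 were higher and 8 lower (median 0.03, and 0.67 with a median shift; adjusted p = 0.752). The integrin ITGB7 lay at 1.02 ± 0.05 and the hyaluronan receptor CD44 at -1.12 ± 0.04. Of 154 KRAB zinc finger genes, 54 were higher and 68 lower (median -0.07 against 0.07 for all genes; adjusted p = 0.0897). With a median shift the list passed the test, with a median of 0.17 against 0.46 for all genes. ZNF91 lay at -2.75 ± 0.08 and ZNF184 at 1.14 ± 0.07.

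Control genes and markers of other cell types gave the following background. Of 16 housekeeping genes, 12 were higher and 3 lower (median 0.43; adjusted p = 0.0975); actin ACTB was higher (0.90 ± 0.04) and the polymerase subunit POLR2A lower (-1.07 ± 0.09). GAPDH was not called (0.03 ± 0.05, higher in 20 of 42 lines) and lay at -0.42 with a median shift, where it was called lower. The elongation factor EEF1A1 was lower by less than 1.5-fold (-0.16 ± 0.03; 36 of 42 lines) and lay at 0.03 with the authors' processed values, and TPT1 lay at -0.58 ± 0.05. T and NK cell markers had 5 genes tested, 3 higher and 1 lower (median 0.14; adjusted p = 0.725). The kinase LCK lay at 1.22 ± 0.05. Monocyte and myeloid markers had 7 genes tested, 3 higher and 3 lower (median -0.14; adjusted p = 0.752). CD68 lay at -1.17 ± 0.06. The 4 fibroblast and epithelial markers tested were all higher, by less than 1.5-fold (median 0.26), and 7 of 11 plasma-cell genes were higher and 3 lower (median 0.59; adjusted p = 0.307). PRDM1 lay at -0.73 ± 0.05 and IRF4 at -0.67 ± 0.04 but IRF4 at 0.10 with a median shift.

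The genes with the highest ratios came from many processes. CBX1, a heterochromatin protein (Entrez Gene 10951, chromosome 17), was 8.30-fold higher in the heavy fraction (log2 3.05 ± 0.09; mean normalized log2 intensity 9.26 against 6.20; adjusted p = 2.09e-29 for a change past 1.5-fold). It was followed by PTPLAD1, a fatty acid elongation enzyme now named HACD3 (2.86 ± 0.09), the mitochondrial elongation factor TSFM (2.59 ± 0.06), CGI-96, now RRP7A (2.54 ± 0.07), and the disulfide isomerase PDIA6 (2.52 ± 0.07). The peptidyl-prolyl isomerase PPIB (2.39 ± 0.09), SERTAD1 (2.39 ± 0.06), the N-terminal methyltransferase METTL11A (2.39 ± 0.06), PSMB3 and PSME2 were also among the highest. HSPBP1, a cochaperone, was among the highest fitted ratios, but was detected on all 42 heavy arrays and on 0 of 42 light arrays. Its ratio was thus a bound, at least 3.30-fold higher (log2 1.72), which does not secure that place. All of these genes were higher in 42 of 42 lines.

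The lowest ratio belonged to SNHG5, a noncoding RNA that hosts small nucleolar RNAs, which was 19.7-fold lower in the heavy fraction (log2 -4.30 ± 0.07; 9.30 against 13.60; adjusted p = 6.42e-43 for a change past 1.5-fold). The mitochondrial carrier SLC25A23 lay at -4.26 ± 0.11, C6orf48, now named SNHG32, at -3.90 ± 0.06, and the lysosomal enzyme IDS at -3.67 ± 0.07. Rows for 4 ferritin heavy chain pseudogenes lay between -3.72 and -3.49: FTHL3P, FTHL12, FTHL11 and FTHL7. BRI3 (-3.51 ± 0.06), CCNB1IP1 (-3.47 ± 0.06) and C9orf16 (-3.43 ± 0.08) were the others of the lowest 12 beside RPL23A, and all 12 were lower in 42 of 42 lines. On the fixed list of noncoding RNAs 4 rows were tested, 1 higher (SNHG8, 0.22 ± 0.06, not called without the pairing of lines or with a median shift) and 3 lower (median -0.35), among them SNHG10 (-0.41 ± 0.11).

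**Figure D3:**
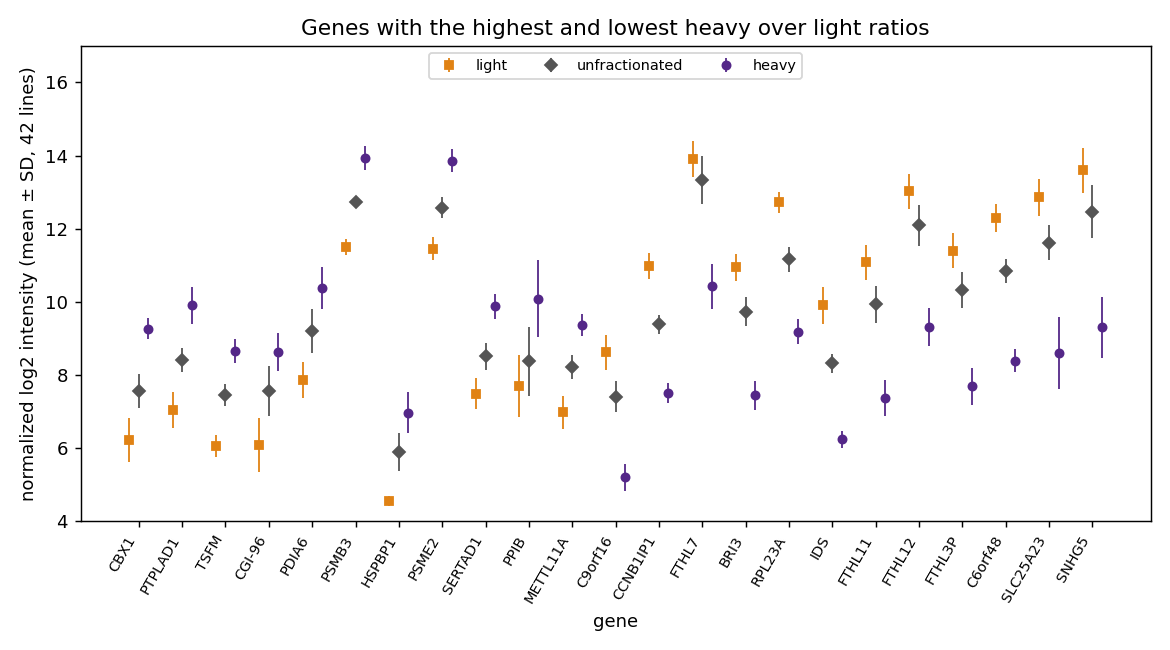
Mean normalized log2 intensity (points; bars are the SD over 42 lines) of genes with the highest and the lowest heavy over light ratios, in the light, unfractionated and heavy preparations. CBX1 lies at 6.20 in the light and 9.26 in the heavy fraction, and SNHG5 at 13.60 and 9.30.

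In the fit by limma, paired by line, 8412 of 9740 genes differed between heavy and light fractions (86.4%; 4603 higher and 3809 lower), and 3187 of them differed by more than 1.5-fold (32.7%; 1670 higher and 1517 lower). In 2415 of the 3187 all 42 lines went the same way. Quantile normalization gives every array the same distribution, so these splits are relative to it: with a median shift the median ratio of all genes was 0.46 in place of 0.07, and 83.0% of the genes past 1.5-fold were higher (3612 higher and 739 lower) in place of 52.4%. With the authors' processed values 1301 genes passed 1.5-fold.

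Comparison of each fraction with unfractionated RNA asked which preparation departed from the whole pool of messages. In the heavy fraction PPIB, a chaperone of the secretory pathway, was raised most (1.72 ± 0.07, log2 with its SE, n = 42 lines), followed by CBX1 (1.71 ± 0.06), PTPLAD1 (1.49 ± 0.07), the initiation factor EIF5 (1.41 ± 0.07) and the histone variant gene H3F3A (1.40 ± 0.04). SNHG5 was lowered most (-3.17 ± 0.06), followed by SLC25A23 (-3.01 ± 0.11), FTHL7 (-2.91 ± 0.09), FTL (-2.88 ± 0.07) and FTHL12 (-2.79 ± 0.08). In the light fraction the zinc finger gene ZNF91 was raised most (1.99 ± 0.07), followed by the pseudogene row RPL23AP13 (1.93 ± 0.07), FLJ42957 (1.74 ± 0.09), the transcription factor ATMIN (1.65 ± 0.07) and RPL32 (1.64 ± 0.07). The remodelling enzyme SMARCA4 was lowered most there (-1.77 ± 0.07), followed by the DNA damage protein TP53BP1 (-1.76 ± 0.07), the Integrator subunit INTS1 (-1.67 ± 0.06), the nucleolar protein NOC2L (-1.60 ± 0.07) and the coactivator PRIC285 (-1.60 ± 0.07).

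Against unfractionated RNA, lists were compared by their medians alone. Ribosomal protein genes had a median of -0.66 in the heavy fraction and 0.30 in the light fraction against unfractionated RNA, the other oligopyrimidine tract genes -0.62 and 0.48, and proteasome subunits 0.65 and -0.52. Other called lists lay nearer 0 in 1 of the fractions, among them mitosis (0.08 in heavy), ribosome biogenesis (0.10 in heavy) and mitochondrial ribosomal proteins (-0.09 in light). Of the 3187 genes past 1.5-fold between fractions, 2972 (93.3%) had their unfractionated mean between the heavy and the light mean. Of 9510 genes tested in both comparisons, 212 were lower in heavy and higher in light RNA than in unfractionated RNA, 128 were the reverse, 24 were lower in both and 10 were higher in both, each past 1.5-fold. Both-lower genes included SMARCA4 (-0.92 ± 0.11 heavy, -1.77 ± 0.07 light), the fatty acid synthase FASN (-1.23 ± 0.11 and -1.44 ± 0.07) and the spindle protein NUMA1 (-1.27 ± 0.10 and -1.002 ± 0.06). FASN and NUMA1, and the both-higher genes KLF6, a transcription factor (1.11 ± 0.06 and 0.89 ± 0.04), and TMED10, a trafficking protein (1.06 ± 0.10 and 1.13 ± 0.10), were chosen after their values were seen.

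**Figure D4:**
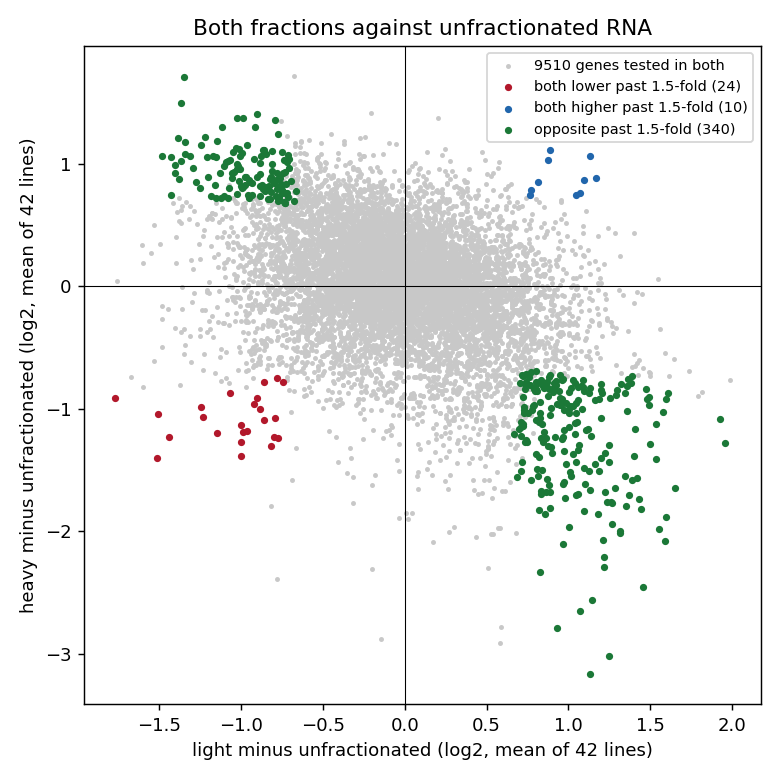
Heavy minus unfractionated against light minus unfractionated log2 difference (means of 42 lines) for 9510 genes tested in both comparisons. Opposite changes past 1.5-fold (212 and 128 genes) outnumber changes in the same direction (24 lower and 10 higher in both).

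Past 1.5-fold, 1163 of 9822 genes differed between heavy and unfractionated RNA (492 higher and 671 lower) and 1336 of 9587 between light and unfractionated RNA (638 higher and 698 lower). These counts were 414 and 409 with the authors' processed values, and 622 and 676 with the background fitted on all rows. With a median shift these splits became 1125 higher and 456 lower for the heavy fraction and 159 higher and 2116 lower for the light fraction. The root mean square distance of a line's profile from its unfractionated RNA was 0.596 ± 0.088 (SD, n = 42) for the heavy and 0.596 ± 0.069 for the light fraction, and 0.888 ± 0.058 between the fractions. The light distance exceeded the heavy one in 26 of 42 lines, with a mean difference of 0.00037 ± 0.0806 (SD; two-sided sign-flip permutation test, p = 0.976). With the authors' processed values the heavy fraction lay farther from unfractionated RNA (-0.0283, p = 0.00011), and also among genes detected on every array (-0.0284, p = 0.0334).

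The spread of the heavy over light ratio between lines was the quantity that the study tested as a trait. The ribosomal protein gene RPS26 had the largest SD over 42 lines among well-detected genes (1.09, around a mean ratio of -1.38), followed by the calcium-dependent kinase gene CAMK1G (0.96), C6orf150 (0.96), ANKRD11 (0.91), the linker histone gene HIST1H1D (0.90), the lysosomal protease CTSZ (0.88), the transcriptional repressor SPEN (0.88) and APBB3 (0.87). Ratios of PSMB3 (SD 0.29) and EEF1A1 (SD 0.16) varied less. The median SD over the genes tested was 0.359 (5% of genes below 0.238, 25% below 0.304, 25% above 0.426 and 5% above 0.584). For 5789 genes with a single probe and detection on at least 90% of heavy and of light arrays, the median SD was 0.353. Bead noise within arrays had a median SD of 0.0937, and the median over genes of its share of the variance was 7.50%. Each line gave 1 array per fraction, so noise of the gradients, RNA preparation and arrays cannot be told apart from differences between lines. The levels themselves had median SDs of 0.349 in unfractionated, 0.385 in heavy and 0.397 in light RNA. With the authors' processed values the median SD of the ratio was 0.152.

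Across lines, some genes had a ratio that followed the gene's own level in unfractionated RNA. The ratio rose with the level for the tight junction gene CLDN23 (slope 0.65 ± 0.07 log2 per log2, adjusted p = 1.86e-09), the muscle protein MYOM2 (0.61 ± 0.07) and the sterol hydroxylase CYP27A1 (0.43 ± 0.05). It fell with the level for the kinase RAGE, now named MOK (-0.52 ± 0.04, adjusted p = 1.17e-13), FAM24B (-0.86 ± 0.07), the LIM protein LMO3 (-0.43 ± 0.04), CLLU1OS (-0.55 ± 0.05) and the homeobox gene HOXB2 (-0.48 ± 0.05). The asparaginase ASRGL1 also passed, but it was detected on 25 of 42 heavy arrays and on 0 of 42 light arrays, so no slope is given for it. The slope differed from 0 for 789 of 9899 genes, 308 with a positive and 481 with a negative slope; with a median shift the balance turned round, to 835 positive and 129 negative. Among 5635 genes detected on every array 170 passed, and 2403 passed with the authors' processed values.

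The ratio table that the authors deposited for 38 of the lines ranked genes much as the ratios computed here did. Across 9727 genes, which are not independent replicates, the mean ratio per gene had a Pearson correlation of 0.965 and a Spearman correlation of 0.980 between the sources, and within single lines the Pearson correlation across genes ran from 0.943 to 0.968 with a median of 0.957. All 3183 genes past 1.5-fold that the table holds had the same sign in both. In the deposited table the mean log ratio was -1.16 ± 0.12 (SD, n = 38) for SNHG5, -0.82 ± 0.08 for RPL22, -0.81 ± 0.12 for PABPC1, 0.64 ± 0.13 for CBX1 and 0.42 ± 0.05 for PSMB1, and 0.00 ± 0.07 for GAPDH. The slope of deposited on computed ratios was 0.218, and the base of its logarithm is not stated. Genes were ranked by between-line SD less alike (Spearman correlation 0.462). The deposited SD rose with the unfractionated level across genes (0.692), while the SD computed here fell slightly (-0.188).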

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

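Of the values given for gene lists under the alternatives, 302 stayed on their side of the threshold and 20 became calls. Another 14 lost a call (10 of them with the estimated correlation) and 1 reversed. The 302 include lists not called whose median changed sign. With a median shift the median of genes with upstream reading frames went from -0.27 to 0.12, and with no filter that of histones from 0.12 to -0.003. Of the values for named genes 1371 stayed on their side, 6 lost a call and 4 reversed. The 20 gained calls were of 10 lists. The spliceosome list gained 6: with a median shift, the authors' values, no filter, detection on every array, no replicate block and the background fitted on all rows. With a median shift and with no filter the iron-responsive, secretory, cytosolic chaperone and cholesterol lists were also called, and the iron-responsive list without the replicate block too. The interferon list was called with a median shift, the histone list with detection on every array, and the class II, glycolysis and housekeeping lists with no filter. Background fitted on all rows, detection by signal over background and leaving out the lines with arrays standing apart were chosen after seeing the data. Averaging all probes of a gene was not run, since the deposited rows are already one per gene, nor was a slide term, since slides were not used here. The signal over background limits the ratios of dim genes; unless the construction of a setting shows it, the cause was not tested. Of 3187 genes past 1.5-fold between heavy and light RNA, raw log2 signals with quantile normalization shared 2377 of their 2377, the authors' processed values 1269 of their 1301, the 38 lines with deposited ratios 3111 of their 3142, and a median shift 2343 of its 4351.

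With quantile normalization and no background correction, the median between-line SD was 0.273, 1184 slopes were called, and the correlation with the deposited ratios was 0.994. With a median shift, 2275 genes passed 1.5-fold between light and unfractionated RNA and the SD was 0.412. GAPDH (-0.42), HK2 (0.23), IRF4 (0.10, not called) and the KRAB zinc finger list (0.17) changed sign there. So did the medians of the upstream reading frame, selenoprotein, NF-kB and AU-rich lists, which were called neither way. The median of all genes went from 0.07 to 0.46, so HK2, IRF4 and the KRAB list still lay below it, and the KRAB list passed the test. The slopes turned from 308 positive and 481 negative to 835 and 129. With the authors' processed values, 1301 genes passed between heavy and light, 414 between heavy and unfractionated and 409 between light and unfractionated RNA, the distance difference was -0.0283 (p = 0.00011), the SD 0.152, the slopes 2403, the correlation with the deposited ratios 0.958, and EEF1A1 lay at 0.0272. Medians of called lists moved as well. The ribosome biogenesis median went from 0.60 to 0.23 with the authors' values, 0.25 with the background fitted on all rows and 1.17 with a median shift. In the same order the mitosis median went from 0.56 to 0.25, 0.26 and 1.23, and the class I median from 0.52 to 0.25, 0.24 and 1.02. With no filter on dim genes, 18 lists and 1514 slopes were called and the SD was 0.301. With detection required on every array, fewer genes were tested: 5010 differed from 0 between heavy and light RNA, 170 slopes were called, the SD was 0.342 and the distance difference -0.0284 (p = 0.0334). Against 1.2-fold, 5766, 3683 and 4097 genes passed in the comparisons of heavy with light, heavy with unfractionated and light with unfractionated RNA, and against 2-fold 1351, 222 and 187. With an estimated correlation 0 lists were called. As Spearman correlation the comparison with the deposited ratios gave 0.980. With the background fitted on all rows, 1660, 622 and 676 genes passed in the same order, 2707 slopes were called, the SD was 0.174 and the distance difference -0.0218 (p = 0.0105). Without the replicate block that pairs the arrays of a line, 2702 genes passed 1.5-fold between heavy and light RNA, all among the 3187, and SNHG8, CDH1, CDC42BPA, CST3 and S100A9 were no longer called.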

Other observations

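Chosen after the result was seen were the tests of dim signals over all genes with a called slope and as the whole cause, of a global difference between lines, of brightness for noncoding RNAs and of noise in shared arrays; the others were set down before. Noncoding RNAs as a class lay low in the heavy fraction. Of 49 rows that the reference annotation classes as long noncoding RNAs, 43 were lower and 5 higher than in the light fraction, with a median log2 ratio of -0.78, and 25 lower and 1 higher passed 1.5-fold. Besides SNHG5 and C6orf48 they held C17orf45, now named SNHG29 (-3.37 ± 0.05, SE, n = 42 lines, lower in all 42), chosen after its value was seen. Low brightness is an unlikely source of the shift: 0 of 10000 random lists of protein-coding genes of the same brightness had a median as low, the lowest being -0.35. The median was -0.48 without background correction, -0.58 with a median shift, -0.12 with the authors' processed values and -0.08 with the background fitted on all rows, so its size depends on the processing, and the cause was not tested. Under each of these 0 of 10000 random lists had a median as low, the lowest being -0.23, -0.15, -0.065 and -0.044 in the same order. A lack of ribosomes on these RNAs was not measured separately and stays a hypothesis.

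Another group was that of genes whose span in the reference annotation holds a small nucleolar RNA gene. Ribosomal protein genes and the listed oligopyrimidine tract genes were left out first. Strand and introns were not checked, so some of these hosts by span may not be true hosts. Several had large ratios in favour of the light fraction, among them CCNB1IP1 (-3.47 ± 0.06), the poly(A)-binding protein PABPC4 (-3.08 ± 0.07) and C19orf48 (-2.75 ± 0.05), the latter pair chosen after their values were seen. Others had large ratios in favour of the heavy fraction, among them PTPLAD1 (2.86 ± 0.09) and SNRPB (2.11 ± 0.04). Over 283 such hosts 119 were lower and 118 higher, with a median of -0.03, and past 1.5-fold 42 were lower and 45 higher. Of 10000 random lists of the same brightness 98.3% had a higher median, with a median of 0.08 and a lowest of -0.09; this lies between the bounds set before, so whether hosts as a class may lie lower was not settled.

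Pseudogene rows lay low in the heavy fraction: of 131 tested, 74 were lower and 44 higher, with a median of -0.45, and 5 ferritin heavy chain pseudogenes lay between -3.72 and -2.93. A candidate explanation is signal from the parent gene's message on the pseudogene probe. Over 56 pseudogene and parent pairs outside the ferritins, the unfractionated levels had a median correlation across lines of 0.323. The highest of 2000 random pairings, which were drawn over all 61 pairs with the ferritins included, was 0.141. The ratios of a pair went together across the 56 pairs (Spearman rho 0.659, two-sided permutation p = 1e-05, the smallest 100000 permutations can give). Some pairs share a parent row, as those of RPL23A do, so pairs are not independent units and this p may be too small. For the 5 ferritin rows the parent FTH1 has no row of that name, so the explanation was not tested for them. Paired with the light chain FTL instead, they had a median correlation of -0.056, and the median over all 61 pairs was 0.234, below the 0.3 set as the bound. The ferritin rows correlated with each other with a median of 0.54 and a lowest of -0.05. Whether the pseudogenes themselves also make RNA with that ratio stays open, and no biological explanation was tested.

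Genes lower in both fractions than in unfractionated RNA were 24, among them ANKRD11, the talin gene TLN1, the pericentrin gene PCNT and EIF3A, named after their values were seen. Independent lists would share 49.1 genes, and for genes higher in both the count was 10 against 32.3. The 2 differences were not independent, with a correlation across genes of -0.365, and of -0.374 at the median with fractions from different lines. Whether the overlap was an excess therefore cannot be told from independent lists. Both comparisons share the unfractionated arrays. With the fractions taken from different sets of 21 lines in 20 draws, the overlap was 14 at the median (8 to 21) against 31.9 for independent lists, a ratio of 0.439 where the same lines gave 0.489. The overlap relative to independent lists was thus 0.891 of that with shared arrays at the median (0.530 to 1.26), which argues against noise in the shared arrays as its source. The bound set before, an overlap of at most the independent number, was met without shared arrays but also with them, so it decides nothing. A median of 13.5 of the genes were among the 24. A property that all unfractionated preparations share was not tested. Over 312 genes whose names state a protein mass, larger proteins tended to lie lower in both fractions (Spearman rho of mass with the mean of both differences -0.255, permutation p = 3e-05, adjusted p = 0.00012 over 4 relations; -0.264 to -0.214 under 4 other normalizations), while mass and the heavy over light ratio were not related (rho 0.01, p = 0.793); genes are not independent replicates. The rho of -0.255 lies between the bounds set before, so it does not decide on long messages as a source. For 58 genes of 100 kDa or more the medians were -0.25 in heavy and -0.37 in light RNA, and for 80 genes under 25 kDa 0.08 and -0.14, but 2 of the 24 genes state a mass, so whether long messages are a source for them stays open.

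The slopes of the ratio on the unfractionated level may in part come from dim signals, which draw both fractions together in lines where a gene is dim. The slope had the sign of the mean ratio in 82.0% of the 789 called genes (647), against 56.5% of the genes not called, which is what that source predicts. Whether it was the whole cause stays open. Among genes detected on every array the calls came to 21.5% of the number (170 of 789), and 67.1% of these had the sign of the mean ratio, against 53.6% of genes not called. That lies between the bounds set before, so dim signals are not excluded for them either. Removing the first principal component of the ratios (18.1% of their variance) left 855 calls, a loss of -8.37%. The component was not shown to hold gradient quality, so this does not decide on a global difference between lines in that quality. A biological link between a message's level and its place on polysomes was not tested apart from these and stays open.

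Chance was examined by swapping the fractions at random within lines, in 100 draws with the real one included. It can be excluded for the 3187 genes past 1.5-fold between heavy and light RNA (highest of the other draws 0), for the 1163 between heavy and unfractionated RNA (highest other 0) and for the 1336 between light and unfractionated RNA (highest other 0). It can be excluded for the 8412 genes that differed from 0, where the highest other was 6966, since draws that leave more lines unswapped than swapped keep part of the difference. Chance was not excluded for the 10 gene lists called with the preset correlation, but these draws cannot decide it. Of the 100 draws 16 gave as many, and the highest other gave 14. Draws with unequal numbers of swapped and unswapped lines keep part of the real pattern. Camera compares a list with the other genes, so a pattern kept at a smaller size can still be called. Chance can be excluded for the 789 slopes, where permuting the lines gave at most 2. In each case where chance is excluded, the real arrangement was the 1 with so high a count.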
